A study of Arabidopsis thaliana with 10 samples.

How the data were processed

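Gene expression was measured in whole young seedlings of Arabidopsis thaliana on Affymetrix ATH1 arrays, a single-colour oligonucleotide array with 22810 probe sets. The 10 arrays fell into 6 groups by genotype and pretreatment as the labels give them. Wild type (Col-0) and the gun1gun5 mutant had 2 arrays for each pretreatment, and the phyA mutant had 1 array for each. FR stands for seedlings that received far-red light ahead of white light, and D for seedlings that went into white light without it. The sample names call the latter Dpretreated, and no label says what D stands for.

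The deposited values were linear probe-set intensities. Each array had been scaled by the authors so that the mean of its values without the lowest and highest 2 percent was about 100 (100.008 to 100.01), and the labels name no summarisation software and no normalization of distributions between arrays. Array medians lay between 35.6 and 40.4, and between 28.9% and 32.3% of the values of an array were under 16. The number of arrays limits the precision of every comparison.

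Probe sets were named from the platform table, with symbols from RefSeq (assembly TAIR10.1) matched by gene ID. Of the probe sets, 13513 matched 1 gene, 503 matched several genes, 64 were array controls, and 8730 were not listed with a gene. Of those with 1 gene, 13436 were found in RefSeq and 77 kept the platform symbol. Many classical genes were among the unlisted probe sets, including PHYA, GUN1 and GUN5, so the mutated genes were not checked here. Of 312 nuclear genes written into the lists fixed before the data were examined, 48 had a named probe set. No coordinates are given because the array annotation names no genome build.

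Values were transformed to log2(value + 16). Probe sets other than controls whose mean over the 10 arrays lay above the 40th percentile, a log2 level of 5.35, were tested, which left 13647 probe sets, 7379 of them with 1 gene. A linear model with the 6 group means was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend with level (4 residual and 6.30 prior degrees of freedom). P-values were adjusted by Benjamini and Hochberg's method over the tested probe sets within each of 8 contrasts, and a probe set passed at an adjusted p under 0.05. All limma tests were two-sided. In the phyA contrasts each lone array was assumed to vary like the arrays of the other groups. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples. Errors are standard errors (SE) of log2 differences from this model. For named genes with every array of a group under 16, the fold is given as at least the mean of the other group over 16. Other folds come from the log2 differences, so they are ratios of values with 16 added. They run smaller than ratios of the values themselves where signal is low.

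The contrasts, the filter, the tests, the gene lists of photosynthesis, pigment synthesis, organelle genomes, stress, metabolism and cell types, and the rule for named genes were chosen before the data were examined. The rule took, in each of 4 contrasts, the 10 higher and the 10 lower single-gene probe sets with the largest log2 difference among those past the threshold. From each of the 24 fixed lists it took up to 4 members past the threshold, or the 2 with the highest mean level if none passed. The lower ends of these rankings were left out for length, and genes named outside the rule are marked as chosen after their values were seen. Since few genes of the fixed lists had a named probe set, 16 further lists were drawn up from gene names before any test. Another 2, the heat-shock family and the cytosolic ribosomal proteins, were drawn up after values were seen.

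Lists with at least 3 tested members were tested with camera in limma at a preset correlation of 0.01, again with the estimated correlation, and with fry, and adjusted over the lists of a contrast. The 2 lists drawn up after values were seen were adjusted apart, over those 2 alone, which is a weaker correction. For phyA a list's median was ranked among the medians of 10000 random lists matched on mean level. Tested on simulated data, the WT contrast recovered 97.0% of probe sets changed by 1 log2 unit and 29.9% of those changed by 0.5. The gun1gun5 contrast recovered 97.0% and 32.8%, the interaction 67.2% and 2.99%, and the phyA contrast 74.6% and 1.49% at these sizes, with between 5.33% and 7.87% false calls over the simulated contrasts. The list test called 20 of 20 lists shifted by 0.3 and 2 of 200 unshifted lists. Simulated probe sets were drawn independently of each other, so this does not show how often lists of correlated genes are called falsely.

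Alternatives were pseudocounts of 1 and 64, quantile normalization between the 10 arrays, no filter and a filter at the 60th percentile, no variance trend, a fit of the compared groups alone, the replicate number as a block, a 2-fold minimum, and leaving out each replicate. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 made the tables of names and the plots.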

Results

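Transcript levels were compared in pools of 300 seedlings grown at 22 °C under continuous light. The series asks how far-red preconditioning, given to block chloroplast development, affects the seedling transcriptome. Far-red light is sensed by phytochrome A, the photoreceptor missing in phyA mutants. GUN1 and GUN5 act in signalling from the chloroplast to the nucleus, GUN5 being a subunit of the enzyme that inserts magnesium into the chlorophyll precursor. There were 2 arrays each for WT_FR, WT_D, gun1gun5_FR and gun1gun5_D, and 1 each for phyA_FR and phyA_D. Across probe sets, arrays of the same group correlated at Spearman's rho of 0.971 to 0.982, and the phyA_FR and phyA_D arrays at 0.972. Values this high were not limited to replicates: phyA_D correlated with WT_D replicate 1 and 2 at 0.957 and 0.971. On the first principal component, with 41.4% of the variance, the WT_FR and gun1gun5_FR arrays lay between -30.2 and -25.3. The other 6 arrays lay between 4.15 and 28.8, with phyA_FR at 18.1 among them. The 25S rRNA control probe set ranged from 314.8 to 3003.8 over the arrays. It differed within groups, at 494.1 and 2367.6 in WT_FR and at 376.7 and 3003.8 in gun1gun5_D. Whether this touches the values of plastid and mitochondrial genes was not tested.

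The first question was which transcripts differ after far-red preconditioning in wild type. Small heat-shock proteins, chaperones that bind unfolded proteins, were among the transcripts that rose most in WT_FR: AT1G52560 rose 6.83-fold (log2 difference 2.77 ± 0.26, SE, n = 2 arrays per group), AT2G29500 by 2.50 ± 0.25 and AT1G53540 by 2.39 ± 0.34. AT1G52560 fell below the filter, and so was not tested, when WT_FR replicate 1, WT_FR replicate 2 or WT_D replicate 1 was left out. AT1G53540 was at 3.09 without WT_D replicate 1 and at 1.69 without WT_D replicate 2. Among those that fell most, the pectin methylesterase ATPMEPCRD was at least 41.9-fold lower, a bound because both WT_FR arrays read under 16, the expansin EXPA8 fell by 2.82 ± 0.29, and the xyloglucan endotransglucosylase XTH32 fell by 2.39 ± 0.19. The antenna proteins LHCB4.3 and LHCB4.2, which bind chlorophyll in photosystem II, fell by 1.68 ± 0.25 and 1.26 ± 0.12. Isocitrate lyase (ICL), a glyoxylate-cycle enzyme that turns seed oil into sugar, rose by 1.76 ± 0.14.

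Others that rose were COR27 (2.70 ± 0.47), a cold-regulated gene, the defensin-like PDF1.4 (2.57 ± 0.22) and AT2G23110 (2.55 ± 0.19), a late embryogenesis abundant protein. The lipid-transfer-like proteins AT4G12490 and AT4G12500 rose by 2.47 ± 0.30 and 2.37 ± 0.30, and AT5G48570, a prolyl isomerase also called ROF2, by 2.29 ± 0.30. The chaperone partner Fes1A rose 4.91-fold (SE of the log2 difference 0.24). Among those that fell were AT3G48970 (-2.91 ± 0.25), the lectin JAL22 (-2.78 ± 0.19), AT5G37790 (-2.78 ± 0.16) and AT4G23670 (-2.75 ± 0.19), a major-latex-protein-like gene. AT4G37220, of the WCOR413 cold-acclimation family, fell by 2.68 ± 0.19, AT1G09310 by 2.52 ± 0.41, and AT5G63180, a pectin-lyase-like gene, by 2.50 ± 0.25. AT1G09310 was at -1.81 without WT_FR replicate 1 and at -3.22 without WT_FR replicate 2.

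In the heat-shock family, drawn up after values were seen, so that its p is no independent evidence in any comparison, 17 of 21 tested members rose in WT and 1 fell, with a median of 1.42 (camera adjusted p = 8.96e-14, and adjusted p = 0.0384 with an estimated correlation). The single tested member of the fixed heat-shock list, ATHSP22.0 of the endoplasmic reticulum, rose by 1.60 ± 0.17. Of mitochondrial genes, 3 of 13 probe sets rose, or 7 adjusted over the list alone, with cox2 at 1.48 ± 0.18, nad6 at 1.23 ± 0.15 and cox1 at 1.06 ± 0.15. Their list median was 0.38 (camera adjusted p = 0.00425, and adjusted p = 0.705 with an estimated correlation). Of genes for elicitor and calcium responses, 6 of 11 rose, and 6 adjusted over the list alone, and 1 fell (median 0.59, adjusted p = 0.00762). That call also ended at adjusted p = 0.705 with an estimated correlation.

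The only tested members of the antenna list were LHCB4.1, LHCB4.2 and LHCB4.3, so it does not speak for other antenna genes. Of these, 2 of 3 members fell, and 2 adjusted over the list alone (median -1.26, camera adjusted p = 0.0131, and adjusted p = 0.705 with an estimated correlation). Of the photosystem and ATP-synthase list, 2 of 5 fell, or 4 adjusted over the list alone, with a median of -0.31 (camera adjusted p = 0.0498, and adjusted p = 0.705 with an estimated correlation). This call ended without WT_FR replicate 2 (-0.30), WT_D replicate 2 (-0.25) or any 1 gun1gun5 array (-0.31). Of nuclear genes for thylakoid proteins, 13 of 37 fell and 4 rose, or 17 and 4 adjusted over the list alone (median -0.24, adjusted p = 0.00798, and adjusted p = 0.741 with an estimated correlation). Without WT_D replicate 2 this thylakoid call ended, at a median of -0.17. Of plastid-encoded genes, 8 of 76 fell (1726 of 13647 over all tested probe sets, a larger share), or 2 adjusted over the list alone. Their median was -0.15 (camera adjusted p = 0.0148, and adjusted p = 0.838 with an estimated correlation), and this call ended without WT_FR replicate 2 (-0.13) or WT_D replicate 2 (-0.09), while the median was -0.24 without WT_D replicate 1. The plastid ATP-synthase subunit atpI fell by 0.89 ± 0.18 and the photosystem I subunit psaC by 0.67 ± 0.14. The atpI call ended without WT_D replicate 2 (-0.69).

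Of the Calvin cycle list, 2 of 3 members fell, and 2 adjusted over the list alone, with SBPASE at -0.47 ± 0.10 (list median -0.32, adjusted p = 0.125). Of 9 tetrapyrrole genes 1 rose and 1 fell, or 1 and 2 adjusted over the list alone. HEMA2, a glutamyl-tRNA reductase at the start of the pathway, was the one that rose, by 0.67 ± 0.12, and the list had a camera adjusted p of 0.948. The anthocyanin enzymes DFR and UF3GT fell by 1.47 ± 0.18 and 1.09 ± 0.17, 2 of 3 in the list and 2 adjusted over the list alone (median -1.09, adjusted p = 0.0377, and adjusted p = 0.705 with an estimated correlation). The anthocyanin call ended without WT_FR replicate 2 (-1.05) or WT_D replicate 2 (-0.84). Of SWEET sugar transporters 5 of 8 fell, and 5 adjusted over the list alone (median -0.83, adjusted p = 0.000128, and adjusted p = 0.230 with an estimated correlation). SWEET17 at -1.84 and SWEET11 at -1.39 are named after their values were seen. AUR1, a mitotic kinase, fell by 0.75 ± 0.13. Of 4 antioxidant genes 1 fell, or 1 rose and 1 fell adjusted over the list alone (adjusted p = 0.920). Of 3 root genes 0 passed in limma over all probe sets, and 0 adjusted over the list alone (adjusted p = 0.948).

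In all, limma called 3053 of 13647 probe sets (22.4%) in WT, 1327 higher and 1726 lower after FR, where 4759 had an unadjusted p under 0.05 and chance gives 682. At least a 2-fold difference was shown by 643 of those called, 235 higher and 408 lower. The labels list 1.5% sucrose in the medium of both WT_D samples and 5 µM norflurazon, an inhibitor of carotenoid synthesis, for WT_D replicate 2, and neither for WT_FR, so the medium differs along with the pretreatment in this comparison. Without WT_FR replicate 2 the count was 2023, and without WT_D replicate 2 it was 1838.

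**Figure D1:**
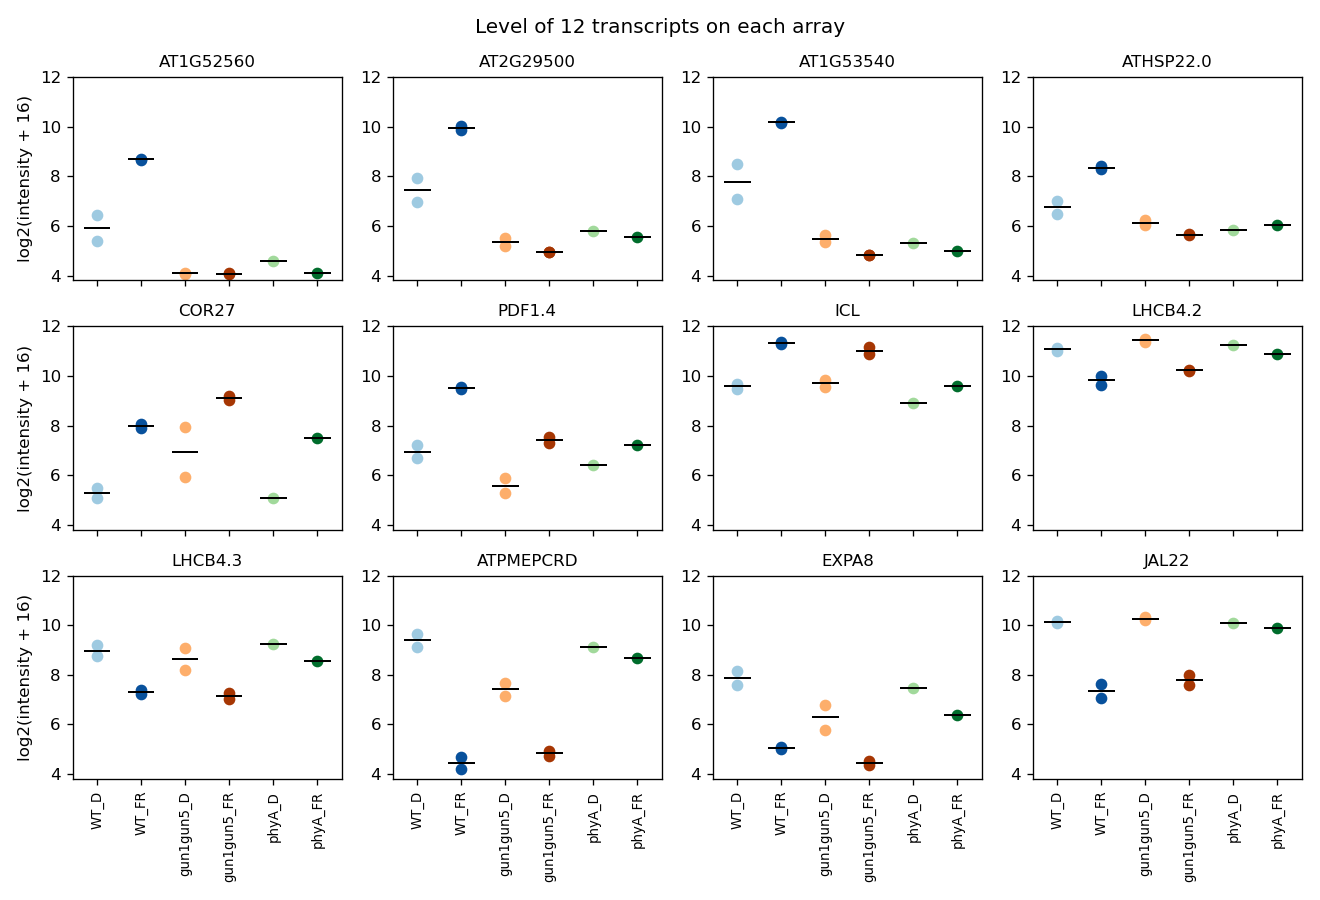
Level of 12 transcripts on each array, as log2(intensity + 16) on the vertical axis, by group on the horizontal axis; dots are arrays and bars are group means. The small heat-shock protein AT1G52560 stands at WT_FR above every other group, while JAL22 is lower in WT_FR and gun1gun5_FR than in the other 4 groups.

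The next comparison asked for the same response in gun1gun5, where the labels list 1 medium for both groups. Cytosolic ribosomal proteins were among the transcripts that rose most: AT5G02450 rose 3.04-fold (log2 difference 1.60 ± 0.19, SE, n = 2 arrays per group), AT3G13580 by 1.51 ± 0.14 and AT4G39200 by 1.47 ± 0.12. The antenna genes LHCB4.2 and LHCB4.3 fell as they did in WT, LHCB4.2 2.32-fold (-1.22 ± 0.12) and LHCB4.3 by 1.49 ± 0.25. JAL22 fell by 2.49 ± 0.19, ATPMEPCRD was at least 9.81-fold lower with gun1gun5_FR under 16, and ICL rose by 1.32 ± 0.14.

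AT2G19970, a relative of pathogenesis-related protein 1, was at least 6.97-fold higher with gun1gun5_D under 16, and PDF1.4 rose by 1.84 ± 0.22. AT1G12010, an ACC oxidase of ethylene synthesis, rose by 1.76 ± 0.13 and AT4G11100 by 1.56 ± 0.26. COR27 rose by 2.17 ± 0.47, its relative AT4G33980 by 1.80 ± 0.43 and the DnaJ-type gene AT1G56300 by 1.80 ± 0.35. These last 3 calls ended without gun1gun5_FR replicate 1 (2.09, 1.65 and 1.81) or replicate 2 (2.25, 1.95 and 1.80). Their values were 3.19, 2.69 and 2.45 without gun1gun5_D replicate 1, and 1.15, 0.91 and 1.16 without gun1gun5_D replicate 2. Among the genes that fell were AT1G09310 (-3.28 ± 0.41), AT1G27030 (-3.12 ± 0.24) and the strictosidine-synthase-like AT3G57010 (at least 5.93-fold, gun1gun5_FR under 16). The latex-protein relatives AT4G23670 and AT3G26450 fell by 3.04 ± 0.19 and 2.22 ± 0.35, and AT4G23680 was 4.93-fold lower (SE of the log2 difference 0.30). AT2G16005 fell by 2.13 ± 0.32. Without gun1gun5_FR replicate 1 the call on LHCB4.3 (-1.38) ended. AT3G26450 and AT2G16005 were at -2.87 and -2.78 without gun1gun5_D replicate 1, and at -1.57 and -1.49 without gun1gun5_D replicate 2.

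All 3 tested antenna members, each an LHCB4 gene, fell, and 3 adjusted over the list alone (median -1.22, camera adjusted p = 0.00203, and adjusted p = 0.441 with an estimated correlation). The third, LHCB4.1 (-0.33), lost its call after quantile normalization (-0.02), and without gun1gun5_FR replicate 1 (-0.36), gun1gun5_FR replicate 2 (-0.30) or gun1gun5_D replicate 2 (-0.28). Of plastid-encoded genes 15 of 76 fell, or 22 adjusted over the list alone (median -0.28, adjusted p = 1.28e-07, and adjusted p = 0.441 with an estimated correlation). Their median was -0.18 after quantile normalization and -0.18 without gun1gun5_D replicate 2. Of the photosystem and ATP-synthase list 4 of 5 fell, and 4 adjusted over the list alone, with a median of -0.35 (adjusted p = 0.00284, and adjusted p = 0.441 with an estimated correlation). This call ended after quantile normalization (-0.17). Of 3 Calvin cycle genes 1 fell, or 3 adjusted over the list alone (median -0.31, adjusted p = 0.0416, and adjusted p = 0.441 with an estimated correlation), a call that ended after quantile normalization (-0.07). It also ended without gun1gun5_FR replicate 1 (-0.31), gun1gun5_FR replicate 2 (-0.30) or gun1gun5_D replicate 2 (-0.20).

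Of 13 mitochondrial probe sets 0 passed in limma, and 0 adjusted over the list alone (median 0.02, adjusted p = 0.596). Of the SWEET transporters 4 of 8 fell, or 5 adjusted over the list alone (median -0.53, adjusted p = 0.00132, and adjusted p = 0.435 with an estimated correlation). The heat-shock family had 3 members that rose and 1 that fell of 21, with a median of 0.04 (adjusted p = 0.439). Without gun1gun5_D replicate 2 its median was 0.16 and the list passed, and without gun1gun5_D replicate 1 its direction turned (-0.09).

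In all, 1970 probe sets (14.4%) passed in gun1gun5, 870 higher and 1100 lower, where 4109 had an unadjusted p under 0.05. At least a 2-fold difference was shown by 353, 96 higher and 257 lower. The count was 506 without gun1gun5_FR replicate 1, 697 without gun1gun5_FR replicate 2 and 675 without gun1gun5_D replicate 2. It was 1251 with no filter on low values.

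The difference between both responses was tested as an interaction, the gun1gun5 response minus the WT response. Small heat-shock genes were among those with a lower response in gun1gun5: the interaction was -3.04 ± 0.48 for AT1G53540, -2.91 ± 0.36 for AT2G29500 (n = 2 arrays in each of 4 groups), -2.51 ± 0.29 for AT5G37670 and -2.10 ± 0.23 for ATHSP22.0. For AT1G53540 it was -3.75 without WT_D replicate 1 and -2.34 without WT_D replicate 2. In the heat-shock family 11 of 21 members had a lower response in gun1gun5 and 1 a higher one (median -1.24, adjusted p = 5.49e-15, and adjusted p = 0.0330 with an estimated correlation). These p-values are no independent evidence, since the list was drawn up after the values of such genes were seen. The largest interactions also took in AT2G23110 (-3.43 ± 0.27), AT5G10695 (-3.31 ± 0.34), the methionine sulfoxide reductase MSRB5 (-2.51 ± 0.27) and AT5G25450 (-2.34 ± 0.29). AT4G12490 had an interaction of -2.43 ± 0.42, a call that ended without gun1gun5_FR replicate 1 (-2.18). AT1G53540, AT2G29500 and AT2G23110 read under 16 in gun1gun5_FR, so their size rests on the pseudocount: it was -3.63, -3.32 and -4.75 with a pseudocount of 1 and -2.42, -2.38 and -2.03 with 64. AT1G52560 read under 16 on all gun1gun5 arrays, where no response can be measured.

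In the other direction, positive interactions were found for AT4G37220 (2.04 ± 0.27), AT3G48970 (2.04 ± 0.35) and AT3G05900 (1.65 ± 0.21). DRT100, a leucine-rich-repeat protein, had 1.57 ± 0.24 and AT4G11100 had 1.76 ± 0.37. The AT3G48970 call ended without gun1gun5_FR replicate 2 (1.89). The AT4G11100 call ended without WT_FR replicate 1 (1.90), WT_FR replicate 2 (1.63), gun1gun5_FR replicate 1 (1.74), gun1gun5_FR replicate 2 (1.78) or gun1gun5_D replicate 1 (1.58). In the mitochondrial list, cox2 had an interaction of -1.84 ± 0.25 and nad6 of -1.22 ± 0.21, 2 of 13 members, or 3 adjusted over the list alone. Its median was -0.35 (adjusted p = 0.00676, and adjusted p = 0.662 with an estimated correlation), and its call ended without gun1gun5_FR replicate 1 (-0.28), while the median was -0.20 without gun1gun5_D replicate 2. The nad6 call ended without gun1gun5_FR replicate 2 (-1.16). For the antenna list 0 of 3 members had an interaction that passed in limma, and 0 adjusted over the list alone (median 0.04, adjusted p = 0.903).

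In all, 385 probe sets had an interaction that passed, 108 with a higher and 277 with a lower response in gun1gun5, where 2195 had an unadjusted p under 0.05. Of these, 164 were higher and 67 lower in WT with no call in gun1gun5, 61 were called in opposite directions and 31 in the same direction. Another 45 were lower and 16 higher in gun1gun5 alone, and 1 was called in neither. The count was 244 without WT_D replicate 2, 149 without gun1gun5_FR replicate 1 and 175 without gun1gun5_FR replicate 2. It was 207 with no filter, and the sucrose listed for WT_D enters this comparison too.

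Both responses also shared genes. Among probe sets higher after FR in WT, 427 were higher in gun1gun5 as well, where chance gives 84.6, and 54 were lower. Among those lower in WT, 649 were lower in gun1gun5, where chance gives 139, and 7 were higher. These chance values take the calls as independent, while both contrasts share the estimated spread of each probe set. Of the 3053 probe sets called in WT, 2560 (83.9%) moved the same way in gun1gun5, 75.2% of the higher and 90.5% of the lower ones. Their median log2 difference, signed by the WT direction, was 0.67 in WT and 0.35 in gun1gun5 (interquartile range 0.12 to 0.62). The choice of these probe sets by their WT calls raises the WT median, so both medians do not measure how much weaker the gun1gun5 response is. Over all tested probe sets the responses correlated at Pearson's r of 0.591, across genes, which are not independent replicates.

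**Figure D2:**
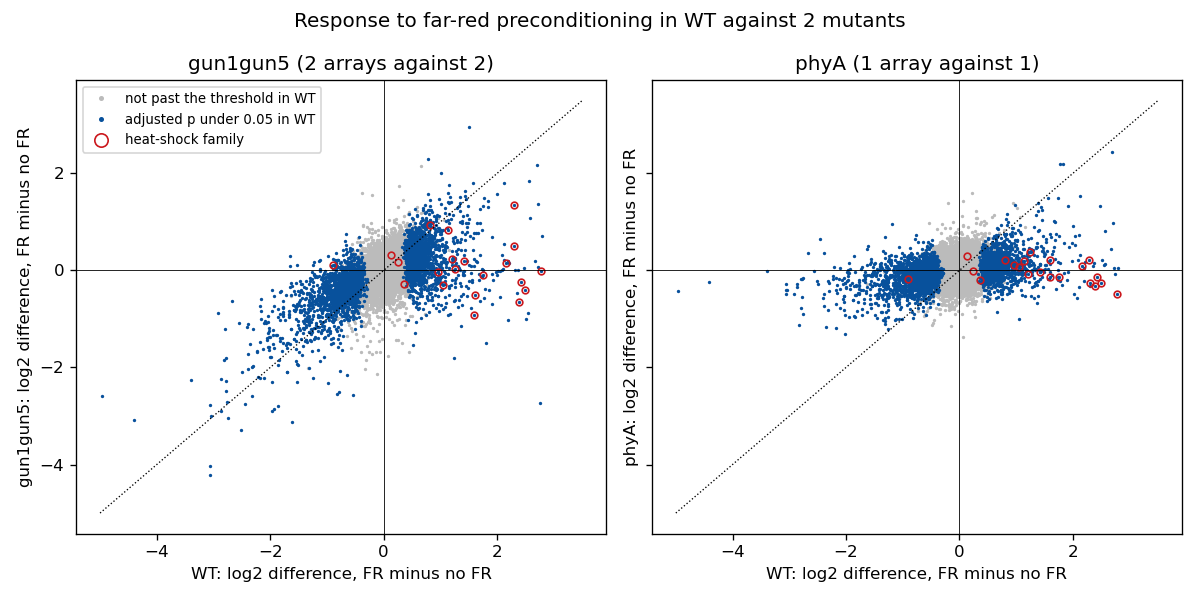
Log2 difference of each tested probe set after FR in WT (horizontal axis) against gun1gun5 and against phyA (vertical axes); blue dots passed in WT, grey dots did not, red circles mark the heat-shock family and the dotted line marks equal responses. Heat-shock genes lie far to the right at WT values up to 2.77 while most lie near 0 in both mutants.

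The phyA comparison asked whether the response appears without the far-red photoreceptor. The rise of small heat-shock genes was not seen there, with log2 differences between phyA_FR and phyA_D of -0.25 ± 0.36 for AT2G29500 and 0.22 ± 0.23 for ATHSP22.0, while AT1G52560 read under 16 on both arrays. The interaction against WT passed for AT2G29500, at -2.75 ± 0.44. ATPMEPCRD differed by -0.43 ± 0.32 in phyA and JAL22 by -0.18 ± 0.27 (interaction 2.60 ± 0.33). With 1 array per group there is no replicate check in phyA, and each lone array was assumed to vary like arrays of the other groups. The sucrose and norflurazon listed for WT_D, and for neither phyA array, enter the interaction against WT.

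Interactions also passed for AT4G37220 (3.03 ± 0.33), AT4G23670 (2.59 ± 0.34), AT3G48970 (2.43 ± 0.43), AT5G37790 (2.24 ± 0.29) and XTH32 (1.91 ± 0.33), the last of which ended without WT_D replicate 2 (1.83). They passed in the other direction for Fes1A (-2.56 ± 0.42), AT2G23110 (-2.44 ± 0.33), cox2 (-1.47 ± 0.31) and ATHSP22.0 (-1.38 ± 0.29). The calls on cox2 and ATHSP22.0 ended without WT_FR replicate 1 (-1.42 and -1.32), WT_FR replicate 2 (-1.51 and -1.44) or either gun1gun5_FR array (-1.47 and -1.38). That on cox2 also ended without either gun1gun5_D array (-1.47), and that on ATHSP22.0 without WT_D replicate 2 (-1.13). COR27 differed by 2.43 ± 0.67 in phyA, and its interaction of -0.27 ± 0.82 did not pass. ICL differed by 0.71 ± 0.19, with an interaction of -1.05 ± 0.24 that did not pass (adjusted p = 0.0571). LHCB4.3 and LHCB4.2 differed by -0.68 ± 0.36 and -0.36 ± 0.17, and their interactions of 1.00 ± 0.43 and 0.89 ± 0.21 did not pass either (adjusted p = 0.298 and 0.0673).

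Among 10000 random lists, the phyA median of the antenna list (-0.36) lay at percentile 0.22, that of the anthocyanin list (-0.60) at 0.03 and that of nuclear thylakoid genes (-0.16) at 0. The plastid-encoded median of 0.02 lay at percentile 82.4 and that of the heat-shock family (-0.03) at 21.9. Random lists take genes as independent, which these ranks from 1 array a side do not test, and in the replicated contrasts 0 of 125 list tests passed with an estimated correlation. The ratio of 3' to 5' actin probe sets, a sign of RNA integrity, was highest on both phyA arrays, at 1.92 and 1.76, against at most 1.58 on the others.

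In the phyA response limma called 0 probe sets, where 699 had an unadjusted p under 0.05 and chance gives 682, and the smallest adjusted p was 0.309. The count became 1 without gun1gun5_D replicate 1 or replicate 2 (COR27, adjusted p = 0.0150 and 0.0155, which enter through the pooled spread). With no filter it was also 1 (AT1G69190, -1.24, adjusted p = 0.0291). The interaction against WT passed for 248 probe sets, 154 higher and 94 lower in phyA, where 2170 had an unadjusted p under 0.05. The interaction count was 165 without WT_FR replicate 2, 134 without gun1gun5_FR replicate 1, 131 without gun1gun5_FR replicate 2 and 66 with no filter. Of the 3053 probe sets called in WT, 68.2% moved the same way in phyA, with a median signed difference of 0.10 (interquartile range -0.04 to 0.28) and a correlation across genes of 0.325.

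After FR, the single phyA_FR array was set against WT_FR with a spread taken from the other groups, which does not separate genotype from that array. AT4G37220 was higher in phyA_FR by 3.28 ± 0.23 and JAL22 by 2.55 ± 0.23 (2 arrays against 1). With 1 side under 16, ATPMEPCRD was at least 24.8-fold higher, AT1G53540 at least 71.0-fold lower and AT1G52560 at least 24.7-fold lower. LHCB4.2 was higher by 1.05 ± 0.15, the plastid ribosomal genes rpl14 and rpl16 by 1.97 ± 0.28 and 1.46 ± 0.24, while ICL was lower (-1.73 ± 0.17). The median of plastid-encoded genes was 0.49 and that of plastid-encoded ribosomal proteins 1.00, both at percentile 100 of the random lists, which take genes as independent. In all, 1722 probe sets passed, 951 higher and 771 lower in phyA, where 3711 had an unadjusted p under 0.05, and 614 differed at least 2-fold. The phyA_FR array also had the highest actin ratio of all, at 1.92.

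A further comparison asked how gun1gun5 differs from WT once both were preconditioned, with no sucrose listed for either. Small heat-shock proteins were lower in gun1gun5_FR: ATHSP22.0 was 6.56-fold lower (log2 difference -2.71 ± 0.17, SE, n = 2 arrays per group). AT1G53540, AT2G29500 and AT1G52560 were lower at least 71.0-fold, 60.8-fold and 24.7-fold, bounds because gun1gun5_FR read under 16. Also lower were the thaumatin-like AT4G36010, at least 11.9-fold for the same reason, the protease inhibitor AT2G38870 at -3.19 ± 0.26 and the glucosyltransferase UGT76B1 at -3.09 ± 0.15. AT4G37220 was 7.89-fold higher (2.98 ± 0.19), and CHLM, a methyltransferase of chlorophyll synthesis, was higher by 0.66 ± 0.10.

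Lower values were found too for AT5G10695 (-4.06 ± 0.24), AT2G32190 (-4.01 ± 0.24) and AT1G19020 (-3.38 ± 0.26). Higher were the zinc-finger gene AT2G29660 (2.32 ± 0.26), AT3G05900 (1.94 ± 0.15), the cysteine-protease-like AT1G29090 (1.73 ± 0.14), AT1G78450 (at least 2.53-fold, WT_FR under 16) and AT2G29670 (1.65 ± 0.32). The linker histone HIS1-3 was higher by 1.53 ± 0.21, AT5G25240 by 1.59 ± 0.19, AT4G38690 by 1.58 ± 0.15 and AT5G53050 by 1.51 ± 0.19. The AT2G29670 call ended without gun1gun5_FR replicate 1 (1.46). AKINBETA1, a subunit of the energy-sensing kinase SnRK1, was higher by 0.85 ± 0.15 and the plastid gene petD by 0.81 ± 0.13. The mitochondrial genes cox2, nad6 and cox1 were lower (-2.25 ± 0.18, -1.27 ± 0.15 and -0.95 ± 0.15).

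In the heat-shock family 17 of 21 members were lower in gun1gun5_FR and 2 higher (median -1.62, adjusted p = 3.51e-13, and adjusted p = 0.0416 with an estimated correlation). Of nuclear thylakoid genes 11 of 37 were higher and 1 lower, or 16 and 1 adjusted over the list alone (median 0.26, adjusted p = 0.000112, and adjusted p = 0.615 with an estimated correlation). Of plastid-encoded genes 4 were higher and 1 lower of 76, or 1 and 0 adjusted over the list alone. Over all tested probe sets a larger share was higher, 1338 of 13647. The plastid-encoded median was 0.14 (adjusted p = 0.0116, and adjusted p = 0.653 with an estimated correlation). This plastid call ended after quantile normalization (0.08), and without WT_FR replicate 2 (0.11) or gun1gun5_FR replicate 1 (0.14). Of 13 mitochondrial probe sets 5 were lower, and 5 adjusted over the list alone (median -0.33, adjusted p = 0.0116, and adjusted p = 0.653 with an estimated correlation). The mitochondrial call ended without gun1gun5_FR replicate 1 (-0.22). In all, 2751 probe sets passed (20.2%), 1338 higher and 1413 lower in gun1gun5, where 4639 had an unadjusted p under 0.05, and 513 differed at least 2-fold, 99 higher and 414 lower. The count was 1340 without WT_FR replicate 2, 974 without gun1gun5_FR replicate 1 and 1309 without gun1gun5_FR replicate 2.

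Without FR, gun1gun5 differed from WT in small heat-shock genes, with a log2 difference of -2.09 ± 0.25 for AT2G29500 (SE, n = 2 arrays per group), and AT1G53540 was 4.92-fold lower. It was 3.02-fold lower without WT_D replicate 1 and 8.00-fold lower without WT_D replicate 2. Lower too were ATPMEPCRD (-1.99 ± 0.23), EXPA8 (-1.59 ± 0.29) and EXPB3 (-1.59 ± 0.20), as were the anthocyanin enzymes DFR (2.00-fold) and UF3GT (-0.84 ± 0.17). The EXPA8 call ended without WT_D replicate 1 (-1.29), and those on DFR and UF3GT without WT_D replicate 2 (-0.75 and -0.59) or gun1gun5_D replicate 1 (-0.85 and -0.89). The UF3GT call also ended without gun1gun5_D replicate 2 (-0.78). In the heat-shock family 9 of 21 members were lower and 1 higher (median -0.21, adjusted p = 0.000735, and adjusted p = 0.217 with an estimated correlation). Its median was -0.14 without WT_D replicate 1, -0.38 without WT_D replicate 2 and -0.45 without gun1gun5_D replicate 2. Of plastid-encoded genes 9 of 76 were higher, or 14 adjusted over the list alone (median 0.25, adjusted p = 1.01e-09, and adjusted p = 0.400 with an estimated correlation). Their median was 0.10 after quantile normalization and 0.15 without gun1gun5_D replicate 2. The photosystem and ATP-synthase, Calvin cycle and nuclear thylakoid lists passed by camera too (medians 0.29, 0.31 and 0.22, adjusted p = 0.00446, 0.0243 and 0.00141), each with adjusted p = 0.400 with an estimated correlation. All 3 calls ended after quantile normalization (0.02, 0.04 and 0.09). They also ended without gun1gun5_D replicate 2 for the first 2 (0.21 and 0.23), and without WT_D replicate 1 for the last 2 (0.25 and 0.17). In all, 1255 probe sets passed, 554 higher and 701 lower in gun1gun5, where 3521 had an unadjusted p under 0.05. Of those that passed, 234 differed at least 2-fold, 54 higher and 180 lower. The sucrose and norflurazon listed for WT_D make this a comparison of medium as well as genotype. The count was 355 without WT_D replicate 1, 631 without WT_D replicate 2, 767 and 763 without gun1gun5_FR replicate 1 and 2 (through the pooled spread), 273 without gun1gun5_D replicate 1 and 584 with no filter.

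No probe set of the fixed lists for nuclear plastid ribosomal proteins, plastid transcription, singlet oxygen, sugar induction, chlorophyll breakdown, defence or seed reserves was both named and above the filter. The lists for carotenoids, light signalling, clock, sugar starvation and stomatal lineage had 1 tested member each, none of which passed in the WT response with all arrays. The carotenoid member LYC (-0.38) passed after quantile normalization (-0.41), without WT_FR replicate 1 (-0.52) and with replicate number as a block.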

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

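The tests that weigh explanations were chosen only after the results were seen, and the lists of the heat-shock family and of cytosolic ribosomal proteins were drawn up then as well.

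Heat-shock genes responded to FR in WT and less in gun1gun5, by the interaction test of the difference itself. The family had a median interaction of -1.24, with ATHSP22.0 at -2.10, AT2G29500 at -2.91 and AT5G37670 at -2.51. AT1G53540 was at -3.04 (-3.75 without WT_D replicate 1 and -2.34 without WT_D replicate 2). AT1G53540 and AT2G29500 read under 16 in gun1gun5_FR, so that their size rests on the pseudocount. AT1G52560 (-2.78) read under 16 in both gun1gun5 groups, where no response can be measured. Sucrose, listed for WT_D alone, stays open and cannot be told apart from the pretreatment within WT: WT_FR exceeded the 6 gun1gun5 and phyA arrays by a median of 2.00 (interquartile range 0.96 to 2.81), and WT_D exceeded them by 0.33 (-0.01 to 0.85), as a family high in WT and lowered by sucrose would. Scaling of the arrays is argued against by a median WT response of 1.44 after quantile normalization. Handling of the seedlings at harvest also stays open and cannot be told apart from the groups, since the labels give no harvest or hybridisation batch and replicates differed by a median of up to 0.28 (0.04 within WT_FR). A part of the genotype in this response is a hypothesis that stays open beside them.

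The WT response as a whole could come from the medium, because the labels give sucrose for WT_D alone. Against this as the whole cause, 83.9% of the probe sets called in WT moved the same way in gun1gun5, where 1 medium is listed for both groups. Norflurazon, listed for WT_D replicate 2, bleaches seedlings and would lower photosynthesis transcripts in that array. Over 40 photosynthesis probe sets its median stood 0.12 above replicate 1 (interquartile range 0.08 to 0.24), which argues against an effect of norflurazon there. A part of the medium in single genes stays open.

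With a spread borrowed from the other groups, the interaction test of phyA against WT called 248 probe sets, or 165 without WT_FR replicate 2, 134 and 131 without gun1gun5_FR replicate 1 and 2, and 66 with no filter, while few moved in phyA. If noise independent between probe sets were the cause, the median change of WT calls in phyA would be about as large as elsewhere. It was 0.10 (interquartile range -0.04 to 0.28) against 0.35 in gun1gun5, which argues against such noise as the whole cause. A deviation of 1 array that many probe sets share stays open, since it would shift the median too. On the first principal component phyA_FR and phyA_D stood at 18.1 and 28.8, and the gun1gun5_D replicates at 4.15 and 16.1. The medium of WT_D, which differs from that of phyA, stays open and cannot be told apart from genotype in the 248 calls: their median change, signed by the WT direction, was 1.45 in WT and 0.64 in gun1gun5, where 1 medium is listed (interquartile range 0.08 to 1.09). The test that chose these probe sets holds the WT response, and 246 of them were called in WT. That choice raises the WT median, so its excess over gun1gun5 does not weigh the medium. Of these 248 probe sets, 193 (77.8%) moved the same way in gun1gun5 as in WT, and 143 passed there in that direction. A dependence of the response on phytochrome A, which the design names, stays an untested hypothesis, for which replicated phyA and WT arrays on 1 medium would be the test.

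The FR response also differed between gun1gun5 and WT in 385 probe sets by the interaction test (244 without WT_D replicate 2, 149 and 175 without gun1gun5_FR replicate 1 and 2, and 207 with no filter). AT4G12500 read under 16 in both gun1gun5 groups, where no response can be measured, and ATPMEPCRD in gun1gun5_FR and WT_FR. AT2G19970 read under 16 in gun1gun5_D and AT2G23110 in gun1gun5_FR. The sizes given below for these genes rest on the pseudocount. All values in this list are interactions, the gun1gun5 response minus the WT response, and do not say that a level was higher or lower in gun1gun5. Positive interactions were those of ATPMEPCRD (2.38), AT3G48970 (2.04), AT4G37220 (2.04), AT4G11100 (1.76), AT3G05900 (1.65), DRT100 (1.57), AT2G19970 (1.51), PMEPCRF (1.4), AT5G48900 (1.38) and EXPB3 (1.33). The PMEPCRF call ended without WT_FR replicate 2 (1.31), WT_D replicate 2 (1.31), gun1gun5_FR replicate 1 (1.48) or gun1gun5_FR replicate 2 (1.32). The AT5G48900 and EXPB3 calls ended without WT_FR replicate 1 (1.27 and 1.14), WT_D replicate 1 (1.21 and 1.35), gun1gun5_FR replicate 1 (1.37 and 1.39), gun1gun5_FR replicate 2 (1.39 and 1.26) or gun1gun5_D replicate 1 (1.08 and 1.01), and EXPB3 also without WT_D replicate 2 (1.3). Without gun1gun5_FR replicate 2 the AT3G48970 call ended (1.89). The AT4G11100 call ended without either WT_FR array (1.90 and 1.63), either gun1gun5_FR array (1.74 and 1.78) or gun1gun5_D replicate 1 (1.58). Negative interactions were those of AT2G23110 (-3.43), AT5G10695 (-3.31), MSRB5 (-2.51), AT4G12490 (-2.43), AT4G12500 (-2.36), AT5G25450 (-2.34), cox2 (-1.84) and nad6 (-1.22). Calls ended without gun1gun5_FR replicate 1 for AT4G12490 (-2.18) and AT4G12500 (-2.44), and without gun1gun5_FR replicate 2 for AT4G12500 (-2.28) and nad6 (-1.16). That on AT4G12500 also ended without WT_D replicate 2 (-2.09).

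Gene lists differed in their response by camera. Mitochondrial genes had a median interaction of -0.35 (adjusted p = 0.662 with an estimated correlation, and ended without gun1gun5_FR replicate 1, at -0.28), cold and dehydration genes of -0.49 (adjusted p = 0.421 with an estimated correlation), and elicitor and calcium genes of -0.45 (adjusted p = 0.488 with an estimated correlation). The mitochondrial median was -0.20 without gun1gun5_D replicate 2, the cold and dehydration median -0.32 without gun1gun5_D replicate 1, and the elicitor and calcium median -0.23 without gun1gun5_FR replicate 1. Plastid-encoded genes had a median of -0.10 (adjusted p = 0.871 with an estimated correlation), and their call ended after quantile normalization (-0.05), and without WT_FR replicate 1 (-0.09), WT_D replicate 1 (-0.03), gun1gun5_FR replicate 2 (-0.09) or gun1gun5_D replicate 2 (0.04). Their median was -0.18 without WT_D replicate 2 and -0.22 without gun1gun5_D replicate 1. Autophagy genes had a median of -0.29 (adjusted p = 0.574 with an estimated correlation), a call that ended after quantile normalization (-0.29), and without WT_FR replicate 1 (-0.25), WT_D replicate 1 (-0.32), gun1gun5_FR replicate 1 (-0.21) or gun1gun5_D replicate 2 (-0.23). Cytosolic ribosomal proteins had a median of 0.16 (adjusted p = 0.544 with an estimated correlation), a call that ended without WT_FR replicate 1 (0.01) or WT_D replicate 2 (0.02), while the median was 0.30 without WT_FR replicate 2 and 0.29 without WT_D replicate 1.

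An Arabidopsis control probe set of the array, left out of the tests, had more signal in some groups than in WT. Its lowest array read 143.4 in gun1gun5_D, and it read 77.8 in phyA_FR and 143.1 in phyA_D, against 11.7 to 19.2 on the 4 WT arrays and 34.6 and 40.5 in gun1gun5_FR.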

How the results depend on the processing

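Limiting the lists to those fixed before the data were examined was chosen after seeing the data; the other alternatives were planned. The WT count stayed within 1.5 times of 3053 under both pseudocounts, quantile normalization, both filters, no trend and a fit of 4 arrays. With a 2-fold minimum, which removes smaller differences by construction, counts were 643 in WT, 353 in gun1gun5, 513 for gun1gun5 against WT after FR, 234 without FR and 614 for phyA against WT. With no filter they were 1251 in gun1gun5, 207 for its interaction, 1 in phyA, 66 for its interaction and 584 for gun1gun5 against WT without FR, and the correlation of responses was 0.529; the cause was not tested. Without 1 array, counts ranged from 1838 to 3071 in WT, 506 to 2160 in gun1gun5, 149 to 369 for its interaction, 0 to 1 in phyA, 131 to 272 for its interaction, 974 to 2762 for gun1gun5 against WT after FR, 273 to 1484 without FR and 1293 to 1763 for phyA against WT. The correlation ranged from 0.544 to 0.599 and the list calls from 28 to 51. Of 125 list tests, which leave out the 2 lists drawn up after values were seen, 48 passed with camera, 0 with an estimated correlation and 31 with fry. The number with camera was 29 after quantile normalization and 17 among fixed lists, of which fewer were tested. Of those 2 lists, the heat-shock family passed by camera with an estimated correlation in WT, the interaction and gun1gun5 against WT after FR (adjusted p = 0.0384, 0.0330 and 0.0416). These p-values were adjusted over those 2 lists alone, a weaker correction than that of the 125 tests. Camera's direction turned for the antenna list in gun1gun5 against WT without FR after quantile normalization (median 0.0210). It turned for some arrays left out in the glycosyltransferases (medians without 1 array from 0.0242 to 0.109) and glutathione transferases (-0.0258 to 0.227) in gun1gun5 against WT after FR and the heat-shock family in gun1gun5 (-0.0950 to 0.161). In the interaction it turned so for plastid ribosomal proteins (-0.231 to 0.129) and plastid photosystem genes (-0.199 to -0.0250); the cause was not tested. With replicate number as a block, counts were 3417, 2362, 501, 0, 357, 3188, 1637 and 1983 in the order above and 41 list calls; the labels do not say that the number marks a batch, and deviations from group means correlated at 0.0642 to 0.187 between groups. No named gene turned direction among those past the threshold under at least 1 setting, where under alternatives 2112 gene values kept their side of it, 267 lost their call and 11 gained one. Signal near the background limits low transcripts: 28.9% to 32.3% of an array's values were under 16.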

Other observations

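The test of scaling was chosen only after the result was seen. Cytosolic ribosomal proteins, which build the ribosomes outside the organelles, were higher after FR in WT and gun1gun5. In this list, drawn up after values were seen, 24 of 118 members rose and 0 fell in WT by limma (median 0.31, adjusted p = 3.28e-11, and adjusted p = 0.281 with an estimated correlation). The WT median was 0.48 without WT_FR replicate 1, 0.14 without WT_FR replicate 2 and 0.16 without WT_D replicate 1. In gun1gun5 47 rose and 0 fell (median 0.46, adjusted p = 5.98e-23, and adjusted p = 0.271 with an estimated correlation). After quantile normalization the medians were 0.31 and 0.47, which argues against scaling as the source. In phyA the median was -0.01, at percentile 44.5 of the random lists.

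COR27 was higher after FR in WT and gun1gun5 (2.70 and 2.17). In phyA its log2 difference of 2.43 was of similar size but did not pass with the pooled spread, which the gun1gun5_D replicates enter. The interaction of phyA against WT did not pass for COR27, so no difference between these genotypes is shown. COR27 stood at a log2 level of 7.98 in WT_FR and 5.28 in WT_D, and at 7.50 in phyA_FR and 5.07 in phyA_D. In gun1gun5_D its replicates stood at 7.96 and 5.92, and those of AT4G33980 at 7.17 and 5.38. AT3G62550, named after its values were seen, stood at 8.32 and 7.09 there.

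Within the plastid genome, all 5 groups of genes were lower after FR in gun1gun5 by camera: photosystem genes (median -0.25, adjusted p = 0.00132), NDH complex (-0.33, adjusted p = 0.0107), RNA polymerase (-0.56, adjusted p = 0.0402), ribosomal proteins (-0.30, adjusted p = 0.0256), and cytochrome and ATP-synthase genes (-0.21, adjusted p = 0.0315). With an estimated correlation each was lost, with adjusted p = 0.441 for the first 3 and adjusted p = 0.548 for the others. Without gun1gun5_D replicate 2 the calls ended for photosystem genes (-0.17, and -0.15 with the call kept after quantile normalization), RNA polymerase (-0.42), ribosomal proteins (-0.12) and cytochrome and ATP-synthase genes (-0.15). Without gun1gun5_FR replicate 2 they ended for NDH (-0.25), RNA polymerase (-0.60), ribosomal proteins (-0.28) and cytochrome and ATP-synthase genes (-0.19). The RNA polymerase call also ended without gun1gun5_FR replicate 1 (-0.42), and the cytochrome and ATP-synthase call after quantile normalization (-0.07). In WT their medians were -0.12, -0.19, -0.14, -0.31 and -0.11, and none passed with all arrays. Without WT_D replicate 1 photosystem genes (-0.19), ribosomal proteins (-0.44) and cytochrome and ATP-synthase genes (-0.23) passed in WT, and photosystem genes also without WT_FR replicate 1 (-0.17). Cold and dehydration genes had a median of -0.39 in gun1gun5, with 4 of 10 lower and 2 higher (adjusted p = 0.0491, and adjusted p = 0.441 with an estimated correlation). That call ended after quantile normalization (-0.33), and without gun1gun5_FR replicate 1 (-0.33), gun1gun5_FR replicate 2 (-0.44), gun1gun5_D replicate 1 (-0.36) or gun1gun5_D replicate 2 (-0.50). COR47, named after its values were seen, was at -2.03 there and at -0.32 in WT, with an interaction of -1.71 (adjusted p = 0.00334).

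Other lists did not pass in WT by camera. Their medians were -0.19 for cell-wall loosening genes, of which 5 of 15 were lower and 1 higher, 0.06 for named plastid ribosomal proteins of the nucleus, -0.29 for glutathione transferases, -0.03 for glycosyltransferases, -0.03 for beta-glucosidases, 0.11 for cold and dehydration genes, -0.09 for autophagy genes and -0.03 for tubulins and histones.

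Single probe sets were picked, after values were seen, for the widest gap between phyA or gun1gun5 and all other arrays. A search over 13647 tested probe sets finds wide gaps by selection, so they are no test. A probe set with no listed gene stood at 4.12 on both phyA arrays and at 7.57 to 8.27 on the other 8. Another stood at 5.95 to 6.13 on the 4 gun1gun5 arrays and at 8.28 to 9.16 on the other 6. The median log2 level of the heat-shock family was 8.41 and 8.36 on the WT_FR arrays, 7.14 and 6.63 on the WT_D arrays, and 6.03 to 6.34 on the other 6.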
